A study of Mus musculus with 9 samples.

How the data were processed

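Gene expression was measured by RNA sequencing in 9 samples of the mouse pancreatic tumor cell line 6620c1, 3 at day 0, 3 at day 2 and 3 at day 14 of culture in nutrient and oxygen deprivation medium. Per the labels, total RNA was extracted with a Qiagen kit, the libraries were made by Novogene and transcripts were quantified with Salmon. The deposited values are gene TPM (transcript abundance corrected for length), scaled by the authors within each sample, and each of the 9 columns was checked to sum to the same total. No scaling between samples was visible. The Salmon version, its index, the genome build and the annotation are not given in the sources used here. The column names carry a prefix, WT, whose meaning is not given there either. The table held 24493 rows named by symbol, 23980 of which were found in the mouse annotation used here, and 0 mitochondrially encoded rows, so the list of mitochondrial mRNAs was not analysed here. TPM keep no read totals, so the depth of each sample is unknown and no counting intervals are given.

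Genes with at least 1 TPM in at least 3 samples were tested, which kept 12693 rows and left out 11800. Values were log2(TPM + 1). All 9 samples were fitted in one model with a mean per day, with limma 3.58.1 in R 4.3.3 and moderated variances with a trend (eBayes). Day 2 was compared with day 0, day 14 with day 0, and day 14 with day 2, and the last of these also tested whether the change from day 0 differed between the times. P-values are two-sided and adjusted by Benjamini and Hochberg over all genes tested, with calls at an adjusted p under 0.05. Lists of genes, 38 in number, were written from textbook knowledge. The 32 with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists within each comparison. With a correlation estimated from the data, camera passed 0 of the lists in each of the 3 comparisons, while 5, 3 and 6 lists had an unadjusted p under 0.05 at day 2 against day 0, day 14 against day 0 and day 14 against day 2, and fry passed 21, 19 and 20. The camera test asks whether a list moved against the other genes. Overlap of the comparisons with day 0 was set against independent lists of these sizes and against 50 simulations of unchanged groups that share a simulated day 0 group.

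Genes were named by a rule. It took (a) for each comparison the 8 genes with the largest rise and the 8 with the largest fall among those past the threshold, with a mean of at least 10 TPM in a group compared and no overlap between the groups' values, predicted genes left out. It took (b) for each list the pair of members with the largest change at day 14 against day 0 and the member with the largest change the opposite way, and (c) all members that passed where 5 or fewer did. Because microRNA and small nucleolar RNA rows filled most places of part (a), the same part was also run without them, a step chosen after the values were seen. The samples, comparisons, tests, lists, the rule and most alternatives were chosen before the data were examined. Car12, Mir6236, Mrc1, Prss2 and Pdgfra were named after their values were seen. A gene that the rule also named is not reported here.

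The alternatives were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 TPM, median-of-ratios scaling, quantile normalization, removal of the 20 most abundant rows, fits without a trend, with robust variances, with sample weights, with the replicate number as a block and with only the groups compared, a test against a log2 fold change of 1 (treat), each library left out in turn, and camera with an estimated correlation, camera on ranks and fry for the lists. The values did not show pairing by replicate number and cannot exclude it. Once the day means were taken out, 4 of 9 samples correlated best with a sample of their own number. Correlations of samples with the same number ran from -0.0709 to 0.318. Removal of Mir6236 and Rn45s, removal of all microRNA and small nucleolar RNA rows, and the overlap under the other scalings were added after the data were seen. The fit was tested on simulated data with 200 changed genes per comparison and the spread of the measured libraries. It recovered most genes changed 2-fold and few or none of those changed 1.5-fold. In the data far more genes were called: 59.0% at day 2 against day 0, 55.1% at day 14 against day 0 and 31.2% at day 14 against day 2. The adjusted threshold is stricter where few genes change, so the simulation cannot tell how many 1.5-fold changes were found here. Smaller changes may still be missed. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.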

Results

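RNA was sequenced from 6620c1, a cell line derived from a mouse pancreatic tumor, at day 0 and after 2 and 14 days of culture in a medium made to deprive the cells of nutrients and oxygen. The medium was DMEM with glucose at 2.5 mM, fetal calf serum at 0.5% and amino acids at 20% of their standard level. The labels list this medium for all 9 samples, day 0 included, and do not say in which medium the cells stood before day 0 or at what oxygen level they were kept. No sample was kept for 2 or 14 days without deprivation, so deprivation and time in culture cannot be told apart. Each day had 3 samples. The labels do not say whether these came from separate cultures, so the limma p-values measure the spread between these samples, which may be technical. The camera p-values at the preset correlation compare a list's genes with the other genes. They rest on the spread between genes and do not measure how a list would vary between samples. Expression was given as TPM, transcript abundance corrected for length and scaled to the same total in each sample, for 24493 gene rows, of which 12693 passed the expression filter and were tested. TPM keep no read totals, so the depth of each library is unknown. Rows with at least 1 TPM numbered 11595 ± 33.5 at day 0, 12060 ± 26.1 at day 2 and 12673 ± 67.5 at day 14 (SD, n = 3). Libraries of one day correlated across genes at r from 0.976 to 0.989 on the log2(TPM + 1) scale, where genes are not independent replicates.

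A single row with a microRNA name, Mir6236, took 10.1% ± 1.62 of all TPM at day 0, 16.8% ± 5.04 at day 2 and 12.2% ± 1.37 at day 14 (SD, n = 3). Its share was 22.5% in day 2 replicate 3 and between 8.27% and 14.6% in the other libraries. Which RNA the reads of this row came from was not tested. All fold changes below are on the log2(TPM + 1) scale, which understates the change of genes with low values. Counts of list members that rose or fell are adjusted over all genes tested, and the count adjusted over the list alone is given where it differed.

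The comparison of day 2 with day 0 asked which transcripts had changed after 2 days in the deprivation medium. Of the 24 tested target genes of HIF, the transcription factors that respond to low oxygen, 21 rose and 1 fell, with a median log2 fold change of 3.03 (camera, adjusted p = 9.98e-13, and adjusted p = 0.22 with an estimated correlation). Bnip3, which codes for a mitophagy receptor, stood at 5.32 ± 1.95 TPM at day 0 and 604 ± 64.9 TPM at day 2 (SD, n = 3), a log2 fold change of 6.62 (SE 0.19, limma, adjusted p = 1.88e-07). Car9, a cell surface carbonic anhydrase, rose from 1.76 ± 0.777 to 33.1 ± 4.07 TPM (limma, adjusted p = 1.31e-06). Ankrd37, a HIF target of unclear function, rose from 3.42 ± 1.60 to 137 ± 12.1 TPM, and Ddit4, an inhibitor of mTORC1 signalling, from 7.89 ± 7.19 to 166 ± 54.4 TPM. The peptide hormone gene Adm rose from 0.228 ± 0.219 TPM to 103 ± 86.6 TPM, with a wide spread between the day 2 libraries (limma, adjusted p = 9.29e-05). All 17 tested genes of glycolysis rose, with a median of 1.41 (camera, adjusted p = 1.43e-09, and adjusted p = 0.279 with an estimated correlation). The lactate exporter Slc16a3 went from 12.7 ± 5.51 to 225 ± 29.5 TPM, and the aldolase gene Aldoc from 3.12 ± 1.72 to 96.7 ± 50.02 TPM. The glucose transporter gene Slc2a1 rose by a log2 fold change of 2.07, from 86.3 ± 4.59 to 369 ± 60.5 TPM (limma, adjusted p = 1.45e-06).

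Genes of the amino acid response rose at the same time. Of 29 tested targets of ATF4 and CHOP, transcription factors induced when amino acids run short or the endoplasmic reticulum is stressed, 21 rose and none fell by this test (22 rose when adjusted over the list alone), with a median of 1.37 (camera, adjusted p = 3.69e-06, and adjusted p = 0.65 with an estimated correlation). Vldlr, a lipoprotein receptor, rose from 1.26 ± 0.36 to 74.03 ± 13.9 TPM and the pseudokinase gene Trib3 from 3.77 ± 2.31 to 117 ± 64.7 TPM. Adm2, a peptide of the same family as Adm that stood outside the lists, rose from 1.25 ± 0.133 to 57.5 ± 17.5 TPM (limma, adjusted p = 1e-06). The cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, split: 9 of 20 rose and 4 fell (camera, adjusted p = 0.551). Cars, for cysteine, rose by 1.38 on the log2 scale, while Farsa and Hars, for phenylalanine and histidine, had log2 fold changes of -1.49 and -1.55 and fell.

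Further lists rose. Among targets of FOXO, transcription factors active when insulin-like signalling is low, 10 of 12 rose, with a median of 1.40 (camera, adjusted p = 0.000154, and adjusted p = 0.306 with an estimated correlation). Gadd45a, a stress-response gene, rose from 9.92 ± 0.722 to 144 ± 56.1 TPM, and the ubiquitin ligase gene Fbxo32 from 0.361 ± 0.0961 to 5.10 ± 0.826 TPM. Of the autophagy and lysosome genes 15 of 28 rose and 3 fell, with a median of 0.43 (camera, adjusted p = 0.00966, and adjusted p = 0.738 with an estimated correlation). Gabarapl1, an autophagosome protein, went from 31.4 ± 6.28 to 78.6 ± 16.1 TPM. Of the JmjC histone demethylases and TET dioxygenases, enzymes that use oxygen, 17 of 21 rose and 4 fell, with a median of 0.97 (camera, adjusted p = 0.000154, and adjusted p = 0.485 with an estimated correlation). Kdm3a, itself also on the HIF list, rose from 16.96 ± 1.43 to 146 ± 28.6 TPM and Kdm7a from 0.643 ± 0.177 to 10.5 ± 2.17 TPM, while Kdm8 fell from 11.7 ± 0.785 to 2.80 ± 0.975 TPM. Cytosolic ribosomal protein genes rose in 19 cases and fell in 4 of 33 (20 and 5 when adjusted over the list alone), with a median of 0.34 (camera, adjusted p = 0.00203, and adjusted p = 0.738 with an estimated correlation). That call was lost under quantile normalization, at a median of 0.15 and an adjusted p of 0.0581.

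Genes of cell division fell. All 24 tested mitosis genes fell, with a median log2 fold change of -4.15 (camera, adjusted p = 2.25e-16, and adjusted p = 0.307 with an estimated correlation). Birc5, a subunit of the chromosomal passenger complex, stood at 228 ± 18.1 TPM at day 0 and 4.73 ± 1.26 TPM at day 2 (SD, n = 3), and Ccna2, the gene for cyclin A2, at 126 ± 19.1 and 2.51 ± 0.791 TPM. The limma adjusted p was 1.88e-07 for Birc5 and 2.64e-07 for Ccna2. The cyclin genes Ccnb1 and Ccnb2 fell, with log2 fold changes of -4.68 and -4.91, as did Cdc20, an activator of the anaphase-promoting complex, at -4.82. All 25 genes of DNA replication and E2F control fell as well, with a median of -2.89 (camera, adjusted p = 3.44e-14, and adjusted p = 0.306 with an estimated correlation). Rrm2, a ribonucleotide reductase subunit, went from 511 ± 86.97 to 14.96 ± 4.67 TPM and Gins1, a part of the replicative helicase, from 56.9 ± 1.47 to 6.15 ± 1.68 TPM. Among the CDK inhibitors and pocket proteins 6 of 10 rose and 3 fell, a list that did not pass (camera, adjusted p = 0.105). Cdkn1a rose from 4.75 ± 0.624 to 60.3 ± 13.4 TPM and Cdkn1c from 0.855 ± 0.172 to 7.25 ± 1.58 TPM, and Cdkn2c fell from 45.7 ± 2.19 to 11.4 ± 1.63 TPM.

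Genes for building ribosomes and respiring fell too. Of 21 ribosome biogenesis genes 19 fell and none rose by this test, with a median of -1.34 (camera, adjusted p = 1.28e-06, and adjusted p = 0.633 with an estimated correlation). Nhp2, a protein of the H/ACA ribonucleoprotein, fell from 401 ± 14.8 to 73.4 ± 13.8 TPM, and Rrp9, a processome component, from 119 ± 2.83 to 25.2 ± 3.30 TPM. Of 27 nuclear genes of oxidative phosphorylation 21 fell and none rose by this test, with a median of -0.61 (camera, adjusted p = 3.69e-06, and adjusted p = 0.307 with an estimated correlation). Under quantile normalization 12 of them fell and 4 rose. Ndufa4 fell from 865 ± 34.3 to 277 ± 34.6 TPM, and Cycs, the gene for cytochrome c, from 139.8 ± 8.40 to 28.5 ± 8.92 TPM. Of 13 heat shock protein genes 7 fell, with a median of -0.41 (camera, adjusted p = 0.0137, and adjusted p = 0.279 with an estimated correlation), including the mitochondrial chaperone pair Hspd1 and Hspe1 at log2 fold changes of -1.48 and -1.33. Genes of the endoplasmic reticulum unfolded protein response went both ways: 4 of 20 rose and 13 fell, with a median of -0.69 (camera, adjusted p = 0.00835, and adjusted p = 0.633 with an estimated correlation). Dnajb9 and Herpud1, both induced by stress of that organelle, rose by 1.80 and 1.33 on the log2 scale, while Sec61b, a subunit of the protein translocation channel, had a log2 fold change of -1.52. The call for this list was lost under quantile normalization, at a median of -0.33 and an adjusted p of 0.08.

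Of 12 targets of YAP and TAZ, regulators that respond to cell density and stiffness, 6 fell, with a median of -0.68 (camera, adjusted p = 0.0469, and adjusted p = 0.738 with an estimated correlation). Leaving out day 0 replicate 3, day 2 replicate 1, day 2 replicate 3 or day 14 replicate 2 ended this call, at adjusted p from 0.0531 to 0.105, as did median-of-ratios scaling (0.0503) and quantile normalization (0.111). Ctgf, a secreted matrix-associated protein, went from 173 ± 28.4 to 39.7 ± 12.1 TPM (limma, adjusted p = 5.85e-05). No other list passed camera in this comparison. NRF2 antioxidant genes split into 5 that rose and 6 that fell of 16, with Slc7a11 (a cystine transporter gene), Hmox1 (heme oxygenase 1) and Gstm1 among those that rose. Hmox1 went from 27.1 ± 8.36 to 395 ± 103 TPM. Of 16 p53 targets 6 rose and 9 fell. Trp53inp1 rose and Gtse1 fell, with log2 fold changes of 3.53 and -4.15. Fatty acid synthesis had 4 that rose and 7 that fell of 14, with the desaturase gene Scd2 up by 1.52 and the elongase gene Elovl6 at -1.84. Fatty acid oxidation had 5 and 1 of 17 (3 and 1 when adjusted over the list alone), and cholesterol biosynthesis 0 and 6 of 22 (0 and 5). Under quantile normalization the numbers that rose and fell were 6 and 4 for NRF2 genes, 6 and 5 for fatty acid synthesis, 10 and 0 for fatty acid oxidation and 3 and 2 for cholesterol biosynthesis.

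Further lists that did not pass at day 2 against day 0 are given as the number that rose and the number that fell. Epithelial genes had 1 and 6 of 18, mesenchymal genes 4 and 5 of 15, and collagens and matrix genes 1 and 4 of 10. Krt7, an epithelial keratin gene, fell from 1513 ± 69.2 to 465 ± 10.8 TPM, and Sparc, a matrix protein gene, from 19.5 ± 0.762 to 7.79 ± 0.79 TPM, while Fn1, the fibronectin gene, rose from 90.7 ± 28.8 to 249.9 ± 50.5 TPM. Genes of the classical pancreatic cancer subtype had 0 and 6 of 18, and those of the basal-like subtype 1 and 1 of 5, namely Slc2a1 and Krt14. Interferon-stimulated genes had 4 and 3 of 12, MHC class I and antigen processing 3 and 3 of 10, chemokines and cytokines 0 and 3 of 16, and NF-kappaB feedback genes 3 and 3 of 13. Quantile normalization gave 3 and 4 for the interferon-stimulated genes, 4 and 2 for MHC class I and 5 and 4 for the NF-kappaB genes, median-of-ratios scaling 3 and 5 for the last, and removal of the 20 most abundant rows 6 and 4 for mesenchymal genes. Immediate early genes had 4 and 2 of 18 (3 and 2 when adjusted over the list alone). Histone and DNA methyltransferases had 5 and 8 of 22, or 9 and 8 without the 20 most abundant rows, where the maintenance methylation genes Uhrf1 and Dnmt1 fell and Ezh1 rose, with log2 fold changes of -4.11, -2.66 and 1.28.

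In all, 3438 genes were higher and 4046 lower at day 2 than at day 0 (limma, adjusted p under 0.05), and 1288 and 1705 of these by at least 2-fold. The median log2 fold change of all tested genes was -0.02. With the 20 most abundant rows removed and the rest rescaled, that median was 0.15 and the split turned to 4563 higher and 3457 lower.

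**Figure D1:**
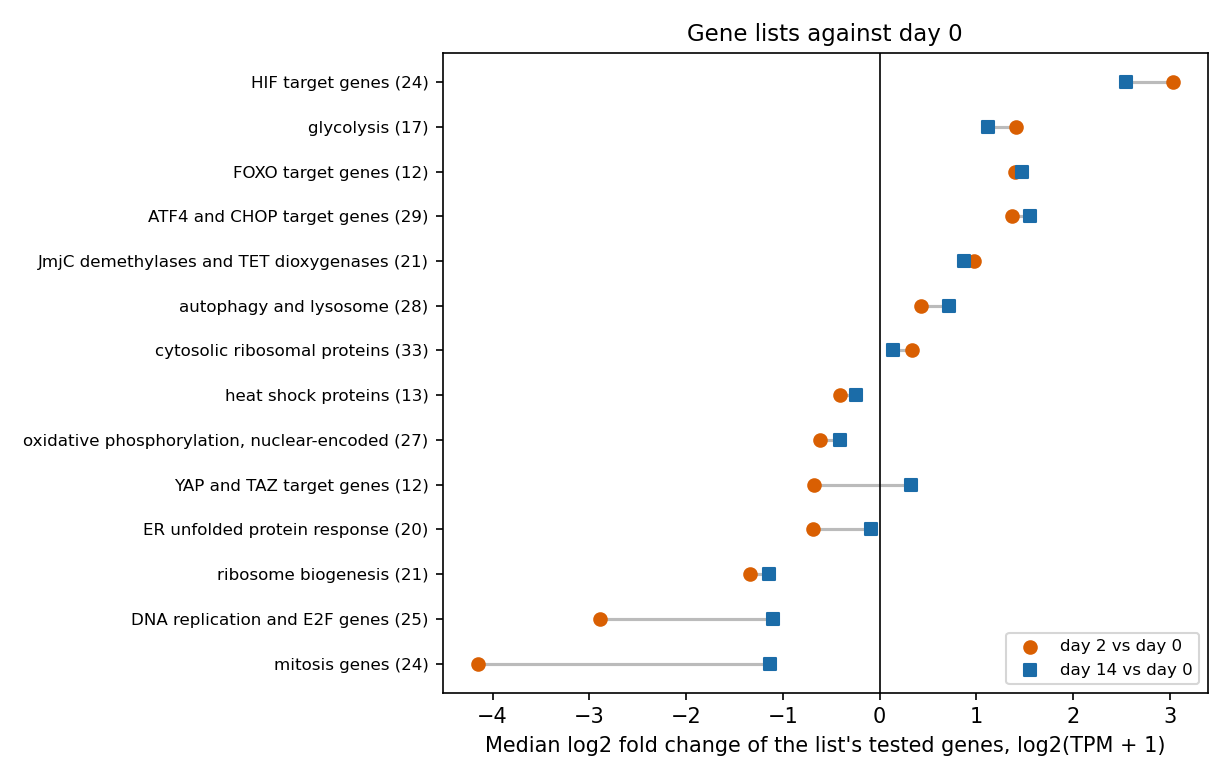
Median log2 fold change, on the log2(TPM + 1) scale, of the tested genes of each list that passed camera at day 2 or day 14 against day 0, with the number of tested genes in parentheses. Circles show day 2 and squares day 14. The mitosis median lay at -4.15 at day 2 and -1.13 at day 14, and the HIF median at 3.03 and 2.55.

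The comparison of day 14 with day 0 asked what the expression state was after 14 days in the deprivation medium. HIF targets were still raised: 21 of 24 were higher than at day 0 and none was lower by this test, with a median of 2.55, or 2.33 above the median of all genes (camera, adjusted p = 7.15e-10, and adjusted p = 0.407 with an estimated correlation). Under median-of-ratios scaling or quantile normalization 1 was lower, Car12. Bnip3 stood at 317 ± 14.8 TPM and Car9 at 59.7 ± 5.68 TPM (SD, n = 3; limma, adjusted p = 1.22e-06 and 3.71e-06). Glycolysis had 13 of 17 higher (14 when adjusted over the list alone), with a median of 1.12 (camera, adjusted p = 0.000123, and adjusted p = 0.431 with an estimated correlation). Slc16a3 stood at 190.2 ± 28.1 TPM and Aldoc at 37.2 ± 12.2 TPM. Targets of ATF4 and CHOP had 21 of 29 higher (23 when adjusted over the list alone), with a median of 1.55 (camera, adjusted p = 2.78e-05, and adjusted p = 0.687 with an estimated correlation). Vldlr stood at 56.97 ± 5.99 TPM, Trib3 at 91.1 ± 29.2 TPM and Adm2 at 47.6 ± 12.6 TPM. FOXO targets had 9 of 12 higher, with a median of 1.48 (camera, adjusted p = 0.00173, and adjusted p = 0.431 with an estimated correlation).

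Autophagy and lysosome genes had 20 of 28 higher and 2 lower than at day 0, with a median of 0.72 (camera, adjusted p = 0.00496, and adjusted p = 0.687 with an estimated correlation). Hexa, a lysosomal hexosaminidase subunit, stood at 17.1 ± 1.27 TPM at day 0 and 56.4 ± 14.8 TPM at day 14, and Gabarapl1 at 111 ± 5.85 TPM, while the cathepsin gene Ctsz was lower, with a log2 fold change of -0.51, a call lost under quantile normalization (adjusted p = 0.0641). JmjC and TET genes had 16 of 21 higher and 4 lower, with a median of 0.87 (camera, adjusted p = 0.0091, and adjusted p = 0.687 with an estimated correlation). Median-of-ratios scaling gave 14 higher and 3 lower for the autophagy and lysosome genes. Kdm3a stood at 124 ± 39.2 TPM, Kdm7a at 8.16 ± 0.978 TPM and Kdm8 at 3.97 ± 0.528 TPM.

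Proliferation genes were below day 0 at day 14. Mitosis genes were lower in 23 of 24 cases, with a median of -1.13, or -1.35 against the median of all genes (camera, adjusted p = 5.49e-12, and adjusted p = 0.431 with an estimated correlation). Birc5 stood at 62.4 ± 8.68 TPM, a log2 fold change of -1.86 from day 0 (SE 0.17, limma, adjusted p = 5.23e-05), and Ccna2 at 36.4 ± 4.58 TPM. DNA replication genes were lower in 24 of 25 cases, with a median of -1.10 (camera, adjusted p = 1.54e-12, and adjusted p = 0.431 with an estimated correlation). Rrm2 stood at 93.9 ± 25.01 TPM and Gins1 at 13.96 ± 1.77 TPM. Mybl2, a cell cycle transcription factor outside the lists, was at 51.9 ± 4.56 TPM at day 0 and 8.44 ± 1.70 TPM at day 14. Ribosome biogenesis genes were lower in 19 of 21 cases, with a median of -1.14 (camera, adjusted p = 4.3e-10, and adjusted p = 0.431 with an estimated correlation), with Nhp2 at 120.3 ± 18.5 TPM and Rrp9 at 43.4 ± 4.99 TPM. Oxidative phosphorylation genes were lower in 15 of 27 cases (17 when adjusted over the list alone), with a median of -0.41 (camera, adjusted p = 1.3e-06, and adjusted p = 0.431 with an estimated correlation). Heat shock protein genes were higher in 2 and lower in 6 of 13 cases, with a median of -0.24 (camera, adjusted p = 0.017, and adjusted p = 0.428 with an estimated correlation). Quantile normalization ended the calls of these last lists, at an adjusted p of 0.0796 for oxidative phosphorylation and 0.204 for the heat shock proteins. It gave 2 higher and 12 lower for oxidative phosphorylation, and median-of-ratios scaling 0 higher and 23 lower there and 0 and 8 for the heat shock proteins.

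Outside the lists, Wfdc2, a secreted protease inhibitor of epithelial cells, fell from 83.98 ± 4.65 TPM at day 0 to 1.35 ± 0.263 TPM at day 14, a log2 fold change of -5.18 (SE 0.14, limma, adjusted p = 3.38e-07). Tnnt2, a cardiac troponin gene, was at 220.0 ± 43.3 and 15.3 ± 6.65 TPM, the interleukin 5 receptor gene Il5ra at 159 ± 36.9 and 22.9 ± 7.93 TPM, and the gap junction gene Gja1 at 66.5 ± 3.04 and 10.2 ± 0.314 TPM. Fabp5, a fatty acid binding protein gene, was at 19.1 ± 3.27 and 2.37 ± 0.801 TPM, and Pcolce2, a collagen processing gene, at 63.6 ± 2.15 and 9.70 ± 3.09 TPM. Pdzk1ip1, a small membrane protein gene, rose from 5.53 ± 0.493 to 127 ± 62.9 TPM (limma, adjusted p = 7.28e-05). Sprr4, a cornified envelope gene, was listed at 0 in all 6 libraries of days 0 and 2 and at 15.5 ± 6.32 TPM at day 14.

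No other list passed camera at day 14 against day 0, with adjusted p from 0.0917 (cholesterol biosynthesis) upwards, although single members changed. Among interferon-stimulated genes 8 of 12 were higher and 2 lower, or 3 and 3 under quantile normalization, with Irf7, a regulator of type I interferon, at 0.666 ± 0.194 TPM at day 0 and 6.36 ± 1.17 TPM at day 14, and with Bst2 lower, at 90.7 ± 9.97 and 46.6 ± 2.13 TPM. MHC class I and antigen processing genes were higher in 7 and lower in 1 of 10 cases, or 4 and 1 under median-of-ratios scaling, with H2-Q4 up by 1.64 and the proteasome subunit gene Psmb10 at -1.43 on the log2 scale. Epithelial genes were higher in 9 and lower in 4 of 18 cases (11 and 4 when adjusted over the list alone), a balance that rested on the scaling, with 7 and 6 under median-of-ratios scaling and 5 and 5 under quantile normalization. Epcam, an epithelial adhesion molecule, rose from 2.23 ± 0.638 to 14.1 ± 4.91 TPM and the transcription factor gene Ehf from 1.004 ± 0.201 to 12.8 ± 7.19 TPM, while Krt7 fell to 514 ± 58.2 TPM. Genes of the classical subtype were higher in 5 and lower in 1 of 18 cases (4 and 1 when adjusted over the list alone), or 2 and 2 under median-of-ratios scaling, with the trefoil peptide gene Tff2 at 0.489 ± 0.412 and 21.7 ± 17.8 TPM. Chemokines and cytokines were higher in 5 and lower in 1 of 16 cases, but the balance turned to 3 and 4 under median-of-ratios scaling and 2 and 5 under quantile normalization, with Ccl20 up from 5.55 ± 3.24 to 36.5 ± 7.18 TPM and Ccl2 down from 6.77 ± 0.792 to 0.481 ± 0.214 TPM. Immediate early genes were higher in 7 and lower in 1 of 18 cases (6 and 1 when adjusted over the list alone), or 5 and 4 under median-of-ratios scaling, with Egr1 at 3.76 ± 0.823 and 38.2 ± 19.3 TPM.

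In all, 4601 genes were higher and 2389 lower at day 14 than at day 0 (limma, adjusted p under 0.05), and 1715 and 604 of these by at least 2-fold. This split rested on the scaling, since the median log2 fold change of all genes was 0.22 in TPM as deposited, -0.05 under median-of-ratios scaling and -0.02 under quantile normalization. Median-of-ratios scaling gave 3115 higher and 4024 lower, and quantile normalization 2884 and 3370.

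**Figure D2:**
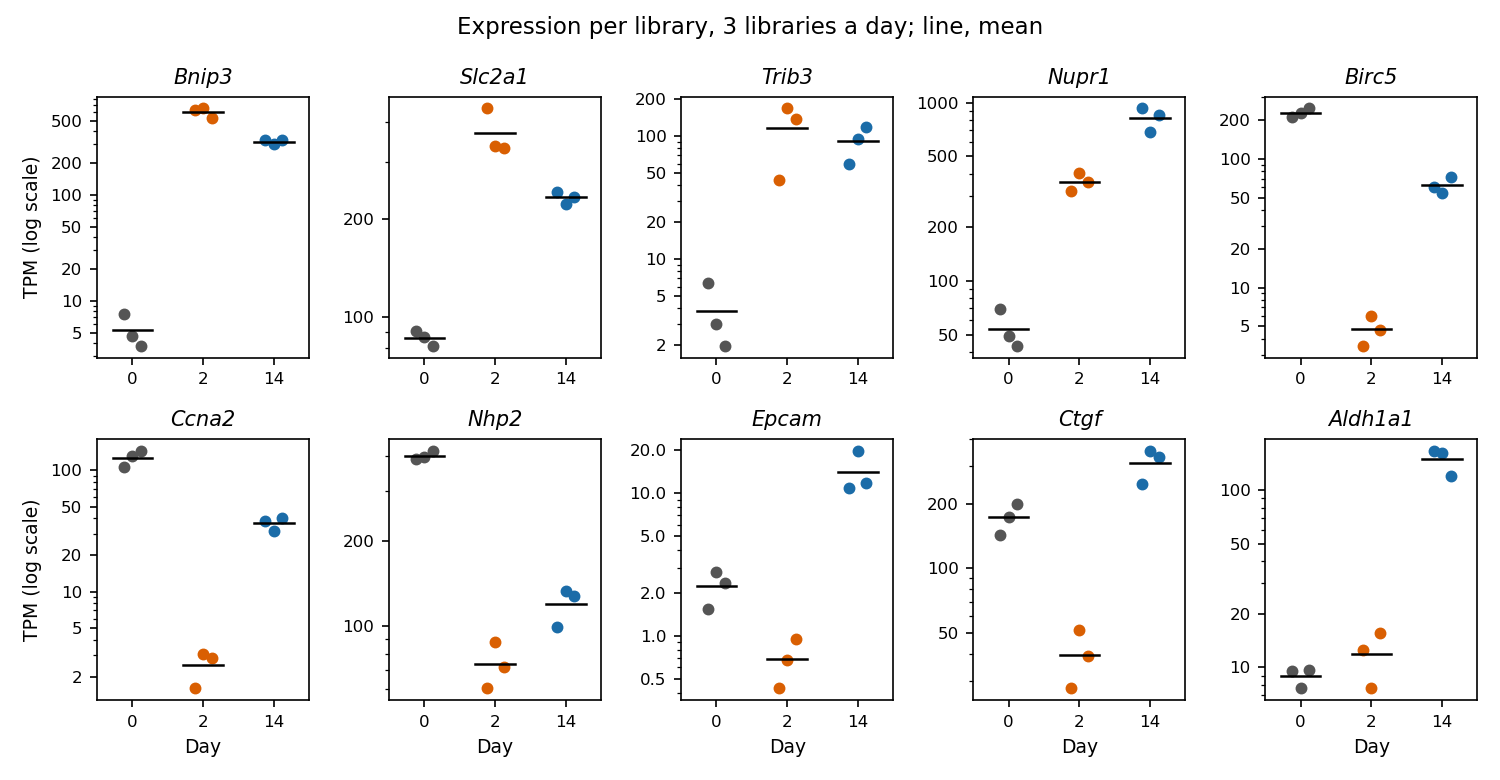
TPM per library on a log axis for 10 named genes at days 0, 2 and 14, with 3 libraries a day (points) and their mean (line). Birc5 went from 228 ± 18.1 TPM at day 0 to 4.73 ± 1.26 at day 2 and 62.4 ± 8.68 at day 14 (mean ± SD), and Bnip3 from 5.32 ± 1.95 to 604 ± 64.9 and 317 ± 14.8.

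The comparison of day 14 with day 2 tested whether the change from day 0 differed between the early and the late time. Mitosis genes were higher at day 14 than at day 2 in all 24 cases, with a median log2 fold change of 3.02, or 2.77 above the median of all genes (camera, adjusted p = 5.44e-23, and adjusted p = 0.23 with an estimated correlation). DNA replication genes were higher in all 25 cases, with a median of 1.70 (camera, adjusted p = 4.67e-15, and adjusted p = 0.23 with an estimated correlation). Under median-of-ratios scaling or quantile normalization 23 of the replication genes and all 24 mitosis genes were higher. Birc5 rose by 3.48 (SE 0.17, limma, adjusted p = 8.81e-06), Ccnb2 by 3.55, Cdc20 by 3.32 and Rrm2 by 2.58 on the log2 scale. Cep55, a cytokinesis gene outside the lists, stood at 3.52 ± 0.667 TPM at day 2 and 49.5 ± 8.03 TPM at day 14. Uhrf1 and Dnmt1 rose by 2.65 and 1.48.

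HIF targets and glycolysis were lower at day 14 than at day 2. Of 24 HIF targets 14 fell and 2 rose, with a median of -0.65 (camera, adjusted p = 4.11e-12, and adjusted p = 0.134 with an estimated correlation). The 2 that rose, the carbonic anhydrase genes Car9 and Car12, did not pass under median-of-ratios scaling or quantile normalization, and Car9 did not pass without day 14 replicate 2 (adjusted p = 0.0511). Bnip3 and Slc2a1 fell, with log2 fold changes of -0.92 and -0.65 (limma, adjusted p = 0.00709 and 0.00383). Of 17 glycolysis genes 10 fell (12 when adjusted over the list alone), with a median of -0.56 (camera, adjusted p = 5.48e-15, and adjusted p = 0.134 with an estimated correlation). Targets of ATF4 and CHOP had a median of 0.19 and did not pass (camera, adjusted p = 0.318), with 3 members that rose, Atf3, Nupr1 and Ppp1r15a, or 1 that rose and 2 that fell under median-of-ratios scaling or quantile normalization. Nupr1, a stress-induced chromatin protein, rose under each of the 4 scalings, from 360.0 ± 42.8 to 823 ± 125 TPM. The calls of Atf3 and Ppp1r15a ended under median-of-ratios scaling and quantile normalization and without day 2 replicate 1 or day 2 replicate 3 (adjusted p = 0.0533 or more), and that of Atf3 also without day 14 replicate 3 (adjusted p = 0.0661). Ribosome biogenesis did not pass either (camera, adjusted p = 0.567).

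Genes of the unfolded protein response were higher at day 14 than at day 2 in 15 of 20 cases (17 when adjusted over the list alone), with a median of 0.72 (camera, adjusted p = 5.67e-05, and adjusted p = 0.331 with an estimated correlation). YAP and TAZ targets were higher in 8 of 12 cases (9 when adjusted over the list alone), with a median of 0.80 (camera, adjusted p = 0.00974, and adjusted p = 0.58 with an estimated correlation), and Ctgf stood at 310.0 ± 55.7 TPM. Collagens and matrix genes were higher in 7 of 10 cases, with a median of 0.77 (camera, adjusted p = 0.0351, and adjusted p = 0.488 with an estimated correlation), a call lost without day 2 replicate 2 or day 14 replicate 1 (adjusted p = 0.144 or more). MHC class I genes were higher in 7 of 10 cases (8 when adjusted over the list alone), with a median of 0.62 (camera, adjusted p = 0.0321, and adjusted p = 0.23 with an estimated correlation), lost without the same libraries (adjusted p = 0.0724 or more). Of these MHC class I genes 4 were higher under median-of-ratios scaling and 2 under quantile normalization. Interferon-stimulated genes were higher in 9 of 12 cases, with a median of 0.53 (camera, adjusted p = 0.0448, and adjusted p = 0.433 with an estimated correlation), lost without any one of day 0 replicate 3, day 2 replicate 2, day 14 replicate 1 and day 14 replicate 2 (adjusted p = 0.0521 or more) and under quantile normalization (0.0857). Of these 4 were higher under median-of-ratios scaling, 3 under quantile normalization and 5 without the 20 most abundant rows. Epcam rose by 3.13, Tff2 by 3.29, Ccl20 by 2.80 and Tnc, a matrix glycoprotein gene, by 1.10 on the log2 scale.

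Of the other lists that passed, ribosomal protein genes were lower at day 14 in 8 of 33 cases (6 when adjusted over the list alone), with a median of -0.16 (camera, adjusted p = 6.29e-13, and adjusted p = 0.331 with an estimated correlation), lost under quantile normalization (adjusted p = 0.308). The number lower was 26 under median-of-ratios scaling, 17 without the 20 most abundant rows and 5 under quantile normalization. JmjC and TET genes were lower in 5 and higher in 2 of 21 cases, with a median of -0.0181 (camera, adjusted p = 0.00232, and adjusted p = 0.518 with an estimated correlation). Median-of-ratios scaling gave 7 of these lower and 0 higher, and quantile normalization 10 and 0. Further calls had medians near 0 or small shifts. Fatty acid oxidation had a median of -0.13 with 1 member higher, Hadhb, and none lower by this test (camera, adjusted p = 0.0321, and adjusted p = 0.719 with an estimated correlation). Hadhb did not pass under median-of-ratios scaling, quantile normalization or removal of the 20 most abundant rows (limma, adjusted p = 0.066 or more). The list call was lost without day 2 replicate 1, day 2 replicate 3 or day 14 replicate 3 (adjusted p = 0.13 or more) and under quantile normalization (0.0857). CDK inhibitors and pocket proteins had 2 higher and 4 lower of 10 (3 and 4 when adjusted over the list alone), with a median of -0.0734 (camera, adjusted p = 0.0354, and adjusted p = 0.23 with an estimated correlation). This call was lost without day 2 replicate 3 or day 14 replicate 2 (adjusted p = 0.0581 and 0.062). It was also lost under median-of-ratios scaling, quantile normalization and removal of the 20 most abundant rows (0.0749 or more). FOXO targets had 1 higher and 2 lower of 12, with a median of 0.0635 although the test put them below the other genes (camera, adjusted p = 0.0351, and adjusted p = 0.518 with an estimated correlation), lost without day 14 replicate 2 (adjusted p = 0.062) and under median-of-ratios scaling (0.106) and quantile normalization (0.114). Under these scalings 5 and 6 FOXO targets were lower and 0 higher, and 3 fatty acid oxidation genes were lower and 0 higher. Oxidative phosphorylation had a median of 0.35 with 14 of 27 higher, or 16 when adjusted over the list alone (camera, adjusted p = 0.0448, and adjusted p = 0.659 with an estimated correlation). This call was lost without any one of 6 libraries (all of day 0, day 2 replicate 2, day 14 replicate 1 and day 14 replicate 2, adjusted p = 0.0518 or more). Median-of-ratios scaling, quantile normalization and removal of the 20 most abundant rows also ended it (0.0857 or more). There 2, 4 and 10 were higher, under median-of-ratios scaling, quantile normalization and removal of the 20 most abundant rows, and 1 was lower.

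In all, 3474 genes were higher and 481 lower at day 14 than at day 2 (limma, adjusted p under 0.05), and 937 and 88 of these by at least 2-fold. The median log2 fold change of all genes was 0.25, and it was -0.01 under median-of-ratios scaling, where 1585 genes were higher and 1487 lower. Quantile normalization gave 1477 higher and 1902 lower at a median of -0.06, and removal of the 20 most abundant rows 2590 and 818 at a median of 0.14. Without day 2 replicate 1 the number of lower genes was 318.

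**Figure D3:**
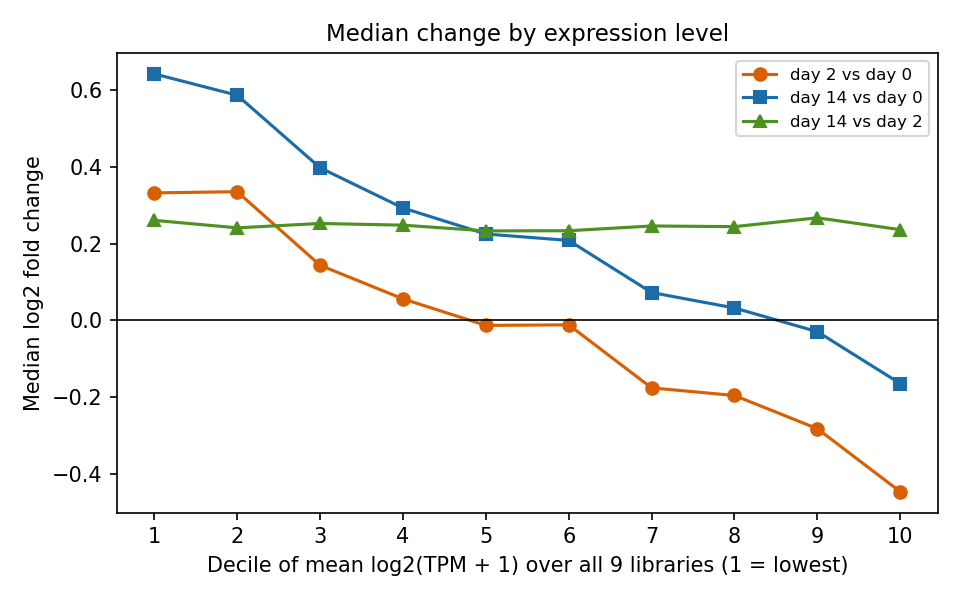
Median log2 fold change of the tested genes in each decile of mean expression, on the log2(TPM + 1) scale, for the 3 comparisons. Day 14 against day 2 lay between 0.23 and 0.27 in all 10 deciles, while day 14 against day 0 ran from 0.64 in the lowest decile to -0.16 in the highest.

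The comparisons with day 0 overlapped: 2976 genes were higher and 2213 lower at both times, where independent lists of these sizes would share 1246 and 762. Simulated unchanged groups shared 0 and 0, but they hold no changed genes to share, so these counts give no baseline. The balance of the observed overlap turned with the scaling, to 2373 higher and 3323 lower under median-of-ratios scaling and 2262 and 2568 under quantile normalization. The fold changes correlated across genes at r = 0.80. Unchanged groups simulated around the day 0 means, with a simulated day 0 group shared by both comparisons, gave 0.50 on average over 50 simulations. That 0.50 comes from the shared group alone. Their covariance was 0.686 against a simulated 0.0389, and 81.8% of genes had the same sign against a simulated 66.7%. The 3 day 0 libraries cannot be split into 2 groups of at least 2, so part of the excess over independent lists may come from the shared controls. A further 101 genes were lower at day 2 and higher at day 14 than at day 0, Epcam among them (its call at day 2 ended with a pseudocount of 5, adjusted p = 0.0855) at 2.23 ± 0.638, 0.686 ± 0.264 and 14.1 ± 4.91 TPM on days 0, 2 and 14, and 5 went the other way. Another 2189 genes passed at day 2 only and 1695 at day 14 only, of which 1215 and 851 also differed between day 14 and day 2. These counts, the 101 and 5 included, are for TPM as deposited and were not repeated under another scaling. There the median log2 fold change of all genes at day 14 against day 2 was 0.25, which favours a fall followed by a rise.

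Most markers of other cell types in the lists were low. All 11 endocrine and all 10 endothelial markers in the table were below 1 TPM in every group mean, as were 15 of 17 acinar, 10 of 12 fibroblast and 11 of 15 macrophage and leukocyte markers. The acinar elastase gene Cela1 stood at 0.395 ± 0.322, 1.79 ± 1.06 and 3.83 ± 0.247 TPM on days 0, 2 and 14, and the other acinar marker above 1 TPM in a group, Prss2, which was below the filter, at 1.001 ± 0.399, 0.371 ± 0.116 and 1.22 ± 0.782 TPM. The fibroblast markers moved apart, with Ly6c1 at 4.51 ± 1.87, 0.407 ± 0.214 and 1.40 ± 0.546 TPM and Pdgfra, also below the filter, at 0.0131 ± 0.0123, 1.39 ± 1.23 and 0.484 ± 0.185 TPM. Of the macrophage markers Csf1r, the receptor for colony stimulating factor 1, stood at 0.215 ± 0.0919, 0.559 ± 0.245 and 3.97 ± 1.495 TPM, Cd68 at 2.20 ± 0.15, 3.70 ± 0.943 and 6.32 ± 1.36 TPM and Cd14 at 60.3 ± 9.16, 39.3 ± 15.6 and 102 ± 34.9 TPM. Csf1r was higher at day 14 than at day 0 (limma, adjusted p = 0.000194) and than at day 2 (limma, adjusted p = 0.00129), and without any one day 14 library it fell below the filter and was not tested. Cd68 was higher at day 14 than at day 0 (limma, adjusted p = 0.00087). Of the 4 tested macrophage and leukocyte markers 3 were higher at day 14 than at day 2, the interval over which the interferon-stimulated and MHC class I lists also passed camera. Besides Csf1r these were Cd14 (limma, adjusted p = 0.0114) and Cd68 (limma, adjusted p = 0.0311). The last call ended under each other scaling, removal of Mir6236 and Rn45s included (adjusted p = 0.0686 or more). It also ended without day 0 replicate 2, day 2 replicate 1, day 2 replicate 2, day 14 replicate 1 or day 14 replicate 2 (adjusted p from 0.0505 to 0.0955). Mrc1, the gene of a mannose receptor of macrophages that was not on the list, ran the opposite way, at 26.6 ± 3.10, 27.99 ± 2.93 and 10.4 ± 3.47 TPM, and was lower at day 14 than at day 0 (limma, adjusted p = 0.000654) and than at day 2 (limma, adjusted p = 0.00117).

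Rows of microRNAs and small nucleolar RNAs took 28 of the 48 places when genes were ranked by fold change in the 3 comparisons. As a group these rows were imprecise: of the 278 tested, 69.1% had a zero in at least 1 library against 1.68% of the other rows, and their median residual SD was 2.02 against 0.195 on the log2 scale. Those that the rule named had, by that rule, no overlap between the values of the days compared. Snora78 stood at 207 ± 18.8, 3.41 ± 5.90 and 126 ± 44.2 TPM on days 0, 2 and 14. Mir8116 stood at 7.01 ± 12.1, 189.6 ± 7.60 and 250.0 ± 8.003 TPM, and Snord110 at 48.8 ± 30.9 TPM at day 0 and was listed at 0 in all libraries of days 2 and 14.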

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

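The tests of explanations in this part were chosen after the results were seen, except the counts over other splits of the samples, which were written before those splits were run but with the real counts known.

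By camera on the direct comparison of day 14 with day 2, 15 gene lists moved against the other genes. Such a call does not show that the list itself changed, since the median log2 fold change of all genes was 0.25. Another scaling ended the calls of ribosomal protein, fatty acid oxidation, CDK inhibitor, FOXO, interferon-stimulated and oxidative phosphorylation genes. Median log2 fold changes of day 14 against day 2 were 3.02 for mitosis genes, 1.70 for DNA replication and E2F genes, 0.80 for YAP and TAZ targets, 0.77 for collagens and matrix, 0.72 for the unfolded protein response, 0.62 for MHC class I and antigen processing, 0.53 for interferon-stimulated genes and 0.35 for oxidative phosphorylation. They were -0.65 for HIF targets, -0.56 for glycolysis, -0.16 for cytosolic ribosomal proteins, -0.13 for fatty acid oxidation, -0.0734 for CDK inhibitors and pocket proteins, -0.0181 for JmjC and TET genes and 0.0635 for FOXO targets. With an estimated correlation none of the 15 passed (lowest adjusted p = 0.134).

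Of 113 named genes weighed here, 69 differed between day 14 and day 2 (limma, adjusted p under 0.05), 41 of them by at least 2-fold in TPM as deposited and with the same call in each of the 4 scalings. This set was first limited to the genes named from the lists by part (b) of the rule, and genes named only by part (c), such as Nupr1, were not in it. After its values were seen, the set was widened to the genes ranked by fold change without small RNA rows. Genes from that ranking include those with the largest changes between day 14 and day 2 among genes past the threshold, so their place in the counts was fixed by how they were picked. The counts are no measure of how often genes differed. Higher at day 14 on the log2 scale were Ccnb2 (3.55), Birc5 (3.48), Cep55 (3.48), Ccna2 (3.43), Cdc20 (3.32), Ccnb1 (3.16), Cdca3 (2.86), Uhrf1 (2.65), Rrm2 (2.58), Gtse1 (2.56), Mybl2 (1.86), Dnmt1 (1.48), Cdkn2c (1.16), Gins1 (1.09) and Hist1h2bj (4.13). Also higher were Pdzk1ip1 (4.14), Myl9 (3.83), Aldh1a1 (3.58), Tff2 (3.29), Epcam (3.13), Ctgf (2.96), Ccl20 (2.80), Fxyd3 (2.52), Hspb1 (2.00), Il5ra (1.82), Pcolce2 (1.71), Csf1r (1.64), Cycs (1.41), Tnc (1.10), Hexa (1.09) and Irf7 (1.06). The fitted value of Sprr4, listed at 0 at day 2, was 3.97 and depends on the pseudocount. Lower at day 14 were Wfdc2 (-3.52), Grem1 (-2.62), Adm (-2.37), Stac (-2.15), Trf (-2.09), Hmox1 (-2.04), Add2 (-1.97), Selenbp1 (-1.93) and Sparc (-1.18). The call of Adm ended without day 2 replicate 1, day 14 replicate 2 or day 14 replicate 3, at adjusted p from 0.085 to 0.101.

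Most genes that differed between day 14 and day 2 were higher at day 14 (3474 against 481). The medians of the 10 expression deciles lay within 0.0205 of that of all genes, which cannot decide whether one scale factor for all genes was the cause. The log2(TPM + 1) scale understates low values, so one factor should give a smaller median in the lowest decile than in the highest. These medians were 0.26 and 0.24. The 20 most abundant rows were not the whole of the shift, since without them the median was still 0.14, with the 9 pairs of libraries between 0.0798 and 0.174. At day 14 against day 0 a single factor and nothing else is argued against, since it would move all genes the same way. The decile medians ran from 0.64 in the lowest decile to -0.16 in the highest, and the largest distance from the median of all genes was 0.42. They sloped at day 2 against day 0 too, from 0.33 in the lowest decile to -0.45 in the highest. A factor beside other changes therefore stays open at day 14. A change in the amount of RNA per cell, which TPM cannot show, stays open and was not tested.

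Mitosis genes were low at day 2 and higher again at day 14. Scaling did not account for this, since under median-of-ratios scaling their median was still 2.77, and a share of cells back in division, beside other changes, stays open with a partial return in every cell, as may death or selection of cells over the 14 days. The explanation by a mix of cells was tested in 4 ways, of which the first was undecided: the share of the way back from day 2 to day 0 was 0.226 ± 0.171 larger for mitosis than for ribosome biogenesis genes (SD, n = 3), with a lowest library at 0.0614 against a bound of 0.1, and 0.274 ± 0.125 under median-of-ratios scaling. In the second, 3 of 29 other lists lay apart from the mitosis genes under both scalings, just at the bound of 3. These were then replaced by tests whose bounds of 5 and 100 genes were set with values close to the final ones in view: 10 of 49 mitosis and replication genes returned by a share apart from the median share, and 152 genes lay at least 2-fold outside both other days in the scaling with the fewest, which argues, with that reserve, only against a mix of day-0-like and day-2-like cells and nothing else.

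MicroRNA and small nucleolar RNA rows led the ranking by fold change, with 28 of 48 places. Low precision of short rows is a candidate explanation. Ranked by p-value, such rows took 1 of 48 places, but a p-value weighs a change against its spread. Rows with a wide spread drop in that ranking whether or not their change is biological, so it cannot decide. A biological change of single small RNAs was not tested apart from this.

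The 6 libraries of each comparison can be split in 10 ways, too few for a share under 0.05. The real split called 7484 genes at day 2 against day 0 and the highest other split 7, so 1 of the 10 splits, the real one itself, reached that count. At day 14 against day 0 these counts were 6990 and 3, and at day 14 against day 2 they were 3955 and 5. Each other split mixes libraries of both days, so the differences between the days enter the spread and keep its count low. The low counts are therefore no measure of what chance would give.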

How the results depend on the processing

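The alternatives were planned, except removal of Mir6236 and Rn45s, removal of microRNA and small nucleolar RNA rows and the overlap under other scalings, which were chosen after seeing the data. Of 377 calls of named genes, 302 were tested in every setting and 248 of these were kept in all of them. In every scaling 375 were tested and 319 kept. Calls not tested throughout fell below a filter or were among rows removed in at least 1 setting. Of 40 list calls, 29 were kept in every scaling and 26 in every setting but the estimated correlation (39 were tested in all of these). Depth is unknown, so what it limits is not known.

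Median-of-ratios scaling gave 4024 lower genes at day 14 against day 0, 1585 higher and 1487 lower at day 14 against day 2, and 3323 lower at both times. It turned Gclm at day 14 against day 0, not called in TPM as deposited, to -0.26. Quantile normalization gave 2884 higher at day 14 against day 0, and 1477 higher and 1902 lower at day 14 against day 2. Without the 20 most abundant rows, 818 were lower at day 14 against day 2. These scalings moved the median of all genes. With only the 2 groups compared, 291 were lower there. Leaving out 1 library each gave 318 (without day 2 replicate 1) to 460 lower. A test against a log2 fold change of 1, a stricter bound, gave 383 higher and 708 lower at day 2 against day 0, 347 and 73 at day 14 against day 0, and 228 and 8 at day 14 against day 2. With a replicate block, the counts higher and lower were 3469 and 4113, 4673 and 2443, and 3526 and 505. The block ended 3 list calls and 6 calls of named genes, and added 1 and 6. At least 2-fold in both, 932 were higher and 540 lower.

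Camera with an estimated correlation called 0 lists at day 2 against day 0, 0 at day 14 against day 0 and 0 at day 14 against day 2. Calls also ended where the estimate lay under the preset 0.01, as for heat shock proteins (-0.0151), CDK inhibitors (-0.00597) and MHC class I (0.00315). Each p-value is adjusted over all lists, so the correlation of other lists can end a call too. Correlation within a list, this adjustment and any other difference between the settings were not told apart. Fry, which does not compare a list with other genes, called 19 lists at day 14 against day 0. Its sign followed the median where camera's was the opposite for p53 targets at day 14 against day 0 (median 0.10), and, at day 14 against day 2, NRF2 genes (0.14), immediate early genes (0.49) and histone and DNA methyltransferases (0.13). Where no cause is named here, the cause was not tested. Leaving out 1 library ended 44 calls of named genes and 8 list calls in at least 1 case, added 38 and 8, and reversed 0.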

Other observations

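The choice of genes in this part was made after the data were seen. A set of genes differed at day 14 from both other days by at least 2-fold (limma, adjusted p under 0.05 in both comparisons, the comparison with day 2 also under median-of-ratios scaling), with a mean of at least 10 TPM in a group and without small RNA and predicted rows. It held 97 genes higher and 10 lower. The comparison with day 0 in it used TPM as deposited, where the median of all genes was 0.22, and the balance moved with the scaling. Without the limits on level and kind of row, 257 genes were at least 2-fold higher and 16 lower than both other days in TPM as deposited, 140 and 28 under median-of-ratios scaling, 110 and 42 under quantile normalization and 259 and 24 without the 20 most abundant rows. Among the higher, Aldh1a1, a retinal dehydrogenase, stood at 8.95 ± 1.14, 11.9 ± 4.02 and 150.5 ± 25.8 TPM on days 0, 2 and 14 (SD, n = 3). The growth factor receptor gene Fgfr3 stood at 2.08 ± 0.326, 1.63 ± 0.637 and 24.9 ± 15.8 TPM, Ndnf at 2.39 ± 0.416, 0.9 ± 0.104 and 18.7 ± 2.65 TPM, and the cornified envelope gene Lor at 1.97 ± 0.461, 3.74 ± 1.04 and 27.7 ± 14.8 TPM. Among the lower, the proteoglycan gene Acan stood at 51.9 ± 5.31, 51.7 ± 5.14 and 15.4 ± 3.07 TPM, the chromatin gene Hmga2 at 121 ± 20.1, 127 ± 45.6 and 47.7 ± 22.1 TPM, and the integrin gene Itga6 at 96.3 ± 9.11, 73.5 ± 2.48 and 33.2 ± 3.998 TPM.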
